A study of Mus musculus with 6 samples.

How the data were processed

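The labels describe total RNA in 6 mouse liver samples, 3 labelled as given vehicle and 3 as given ginkgetin, extracted with a Qiagen column kit and made into libraries with a SMARTer mRNA kit. Per the submitters' processing notes, the genome build was GRCm38 (mm10). The aligner, the counting tool and the annotation are not given in the sources used here. The authors deposited 1 table for the whole series, with a gene name and 6 columns of whole-number counts per gene, not normalized per the file headers and values.

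Of the 6 columns of per-library values, 6 could be matched to no sample or group of the labels by name, and none was used. Column order and expression values were not used to assign them, since the levels of fibrosis genes are the outcome of the study. No value column entered a reported result. The columns were inspected to establish their unit and their total counts. The gene names were compared with the symbols of the reference annotation (GENCODE M21, on GRCm38) and with 47 gene lists fixed before the data were examined. The planned test of counts, the gene list tests and their alternative settings were not run, because they compare the labelled groups.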

Results

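RNA sequencing was carried out on liver tissue of mice with liver fibrosis, to examine what ginkgetin does to the fibrotic liver. Ginkgetin is a biflavone, a dimeric flavonoid found in the leaves of Ginkgo biloba. The labels name 6 liver samples in 2 groups. The control group held 3 samples from fibrotic mice that received vehicle, and the ginkgetin group held 3 samples from fibrotic mice that received ginkgetin at 5 mg/kg per day. The design implies 1 comparison, ginkgetin against vehicle.

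The deposited table listed 33922 gene rows under 33908 different gene names. Of these names, 33269 matched a symbol of the mouse reference annotation. The 6 value columns carried the names TAA and NC, numbered within each name, which occur in none of the sample labels or the design text. TAA is a usual abbreviation of thioacetamide, a chemical used to induce liver fibrosis, but both labelled groups were fibrotic. NC is not explained in the labels. Read as a control, it could name the vehicle group or livers outside the labelled groups. If NC named the vehicle group, TAA would be left for ginkgetin. If TAA named the fibrotic vehicle group instead, NC would be left for ginkgetin. No label gives either meaning, and these readings would give opposite directions of change for every gene. The names therefore did not settle which columns, if any, were vehicle or ginkgetin. The table could also hold a contrast of livers other than the labelled one. None of the 6 columns was assigned to a group.

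No expression level, fold change or test is reported for ginkgetin against vehicle, because the direction and the identity of the comparison could not be established from the labels. The 47 gene lists fixed for the comparison covered matrix, stellate cells, immune and other cell types, metabolism, drug response and sample quality. Together they held 1158 different genes, of which 1155 were listed in the table under a fixed or alternative name. The lists were not tested.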

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

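No paired analysis was possible between the labelled groups because no column was assigned to vehicle or ginkgetin. A fit of the TAA columns against the NC columns under their own names is computable but was left out, since columns that match no labelled sample were not used. The other normalizations, filters on low counts, other tools and the leaving out of each replicate were not run for the same reason.

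The number of gene names found in an annotation was the only reported value computed under an alternative choice. It was 33269 with GENCODE symbols and 26722 with RefSeq symbols, an alternative chosen after seeing the data. It bears on the naming of the rows and says nothing about ginkgetin.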
